A study of Mus musculus with 2 samples.

How the data were processed

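Uteri of untreated CD-1 mice were collected in diestrus and estrus, and 1 Hi-C library per stage was prepared with the Arima HiC kit, per the labels' protocols. Each library was placed in its group by the stage in its label. Whether a library pooled several animals is not given in the sources used here. Tools and build are credited to the submitters' processing notes, which name Juicer and mm10; the aligner, the tool versions and the caller's settings are not given in the sources used here. The deposited lists have the columns that HiCCUPS, the loop caller of Juicer, writes, per the file headers.

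Each deposited list gives 1 loop per line, as a pair of anchors 10 kb wide on the same chromosome. The number of contacts observed at each loop and the number of enriched pixels merged into it are counts made by the authors, without normalization, per the file headers. The contacts expected from each of 4 local neighbourhoods (donut, bottom-left, horizontal and vertical) are a signal computed by the authors' caller on the scale of the raw contacts. The q-values (false discovery rates) for each neighbourhood are those of the authors' caller, and the largest listed were 0.0955 in diestrus and 0.0991 in estrus. The anchor positions, in the deposited files and per the file headers, are of another kind (other: bases, not measurements). Only called loops are listed, so the contacts at a position that was not called are not used here, and an absent loop does not mean absent contacts. Loops reach a list only above the caller's thresholds, so loops close to these thresholds can be called in a single library by counting error. Coordinates are given 1-based on mm10.

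Loops were counted per library and chromosome. A loop was called shared when a loop of the other list had both anchors within 10 kb of its own, measured between nearest edges. Chance sharing came from 1000 random placements of each loop on its chromosome. Strength was the observed number of contacts over the donut expectation. For shared loops, mutually nearest loops were paired, and the log2 ratio of strength was centred on the median over pairs to allow for different depths. Intervals at 95% were Clopper-Pearson for shares, exact Poisson for contacts, exact conditional for ratios of contacts, and binomial order statistics for medians. Those of contacts and their ratios cover counting error only, since read pairs without molecular identifiers are not independent molecules. Those of strength ratios also take the expected contacts as exact. Those of shares, loop numbers and medians treat loops as independent draws, and none covers the spread between animals.

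Gene positions came from a RefSeq table of mouse assembly GRCm38.p6, the assembly that mm10 names. That table as used here has no strand, so the planned test, a transcription start site inside an anchor, was replaced by either end of the gene inside an anchor. This covers 49554 genes on the chromosomes with loops, 21631 of them protein-coding. No genome sequence was used, so the planned search for CTCF and hormone response element motifs was not run. The 14 gene lists, with 278 symbols of which 277 matched, were fixed before the data were examined, as were the groups, main settings and most other settings tried. For each list, loops at its members in estrus minus diestrus were ranked among 10000 random lists of protein-coding genes with the same size and matched total loop number. Loops of a list are sums over its members, so a loop at several members counts for each. Matched sampling was with replacement in large classes of genes.

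Genes were named by a rule fixed before the data were examined. It took genes of the lists with at least 3 loops and a difference of at least 2, up to 6 per list, and Esr1, Pgr and Epas1 whatever their values. It also took the 8 protein-coding genes with the largest excess in each direction, predicted genes aside. Ties were broken by the larger number of contacts and then by name. Loops were ranked only if they had at least 20 contacts and an end of a protein-coding gene in an anchor. From these the rule took the genes at the 5 shared loops with the largest ratio in each direction. It also took those at the 5 strongest loops of each single library. Other list members are named as examples, and the genes at loops of identical position, Pcsk6, Tm2d3 and Cwc22 were chosen after their values were seen. The limits of 50 contacts and 4 times the expected number used for chromosome 7 were also chosen after the lists were seen.

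The methods were tested on simulated data made from the 26240 diestrus loops. All 19699 loops that were kept with a shift of up to 1 bin were found again, which the tolerance guaranteed. Of 6541 removed loops, 2.90% were matched to a neighbour. Among 200 loops planted at 2-fold the median recovered fold was 1.99, and 99.5% passed 1.5-fold. Of 199 planted at 1.5-fold 46.2% passed. Each shifted loop kept its own expected contacts on a common scale. The simulation therefore did not test folds of loops whose background differs between shifted positions. Of 100 unchanged gene lists, 96.0% lay inside the middle 95% of random lists. Alternatives covered the q-value threshold, minimum contacts and strength, tolerance, list length, background, centring and gene assignment. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.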

Results

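Chromatin contacts were mapped by Hi-C, in which DNA segments that lie close together in the nucleus are ligated and sequenced as pairs, in the uterus of untreated CD-1 mice aged 2 months. CD-1 is an outbred stock. One library (n = 1) came from diestrus, the stage of the estrous cycle in which progesterone acts on the uterus, and the other (n = 1) from estrus, which follows the estrogen peak. The question was whether chromatin loops differ between these stages. The diestrus list held 26240 loops with 4533525 contacts, and the estrus list held 24131 loops with 4153485 contacts. The median loop held 125 contacts in either library. These sums cover called loops only, and the full sequencing depth of the libraries is not used here. There were no replicates, so no difference below has a replicate check, and no p-value was computed between the stages. Intervals are at 95%, and none covers the spread between animals. Those of contacts and their ratios cover counting error only, and those of strength ratios also take the expected contacts as exact. Those of shares, loop numbers and medians cover chance over the loops listed. Intervals that compare loop numbers between the libraries count shared loops in both lists, and so are no valid measure of chance.

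Across all protein-coding genes, the largest excess of loops in diestrus was at Tshz2, a zinc finger gene with 13 loops in diestrus and 7 in estrus. It was followed by Flrt2 with 13 and 8, Ppp2r1a with 7 and 2, Ebf1 with 13 and 9, Kctd12 with 9 and 5, Arid5b with 6 and 2, and Top2b with 9 and 5. In all, 24 protein-coding genes differed by 4 or more loops, and among genes with equal differences those with more contacts were named. In the other direction, Cdkal1 had 3 loops in diestrus and 7 in estrus, Ncam1 had 1 and 5, Bco2 had 0 and 4, and Rab11fip2 had 2 and 5. All 11 of these genes differed by at least 2 loops in the same direction under each of the 5 other settings tried. These settings use the same 2 lists, and the genes were picked as the largest differences. Keeping the direction is therefore no test of chance, and no interval is given for these numbers of loops. Over all protein-coding genes, 3027 had more loops in diestrus, 2267 had more in estrus, and 3755 had equal numbers of at least 1. The excess in estrus at Tox, with 0 and 5 loops, Ppp3ca with 0 and 4, Zfp503 with 7 and 10 and Prkg1 with 2 and 6 depended on which bins were assigned to the gene. With gene ends within 5 kb of an anchor, Tox had 7 and 8 loops, Ppp3ca had 8 and 11, Zfp503 had 11 and 12, Prkg1 had 6 and 9, and Bco2 had 3 and 6. With any base of the gene in an anchor, Tox had 8 and 11 and Ppp3ca had 10 and 11. Of the 4 estrus loops at Bco2 and at Ppp3ca, 2 each had a counterpart in the diestrus list at a bin without an end of the gene. For Prkg1, counting every loop with any base of the gene in an anchor gave 20 loops in diestrus and 18 in estrus, the opposite order. The same count gave 14 and 29 for Cdkal1, and 19 and 8 for Rarb. Of the 35 genes with a difference that the list and genome-wide rules named, 32 kept its direction under all 5 settings, 21 of them with a difference of at least 2 loops.

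**Figure D1:**
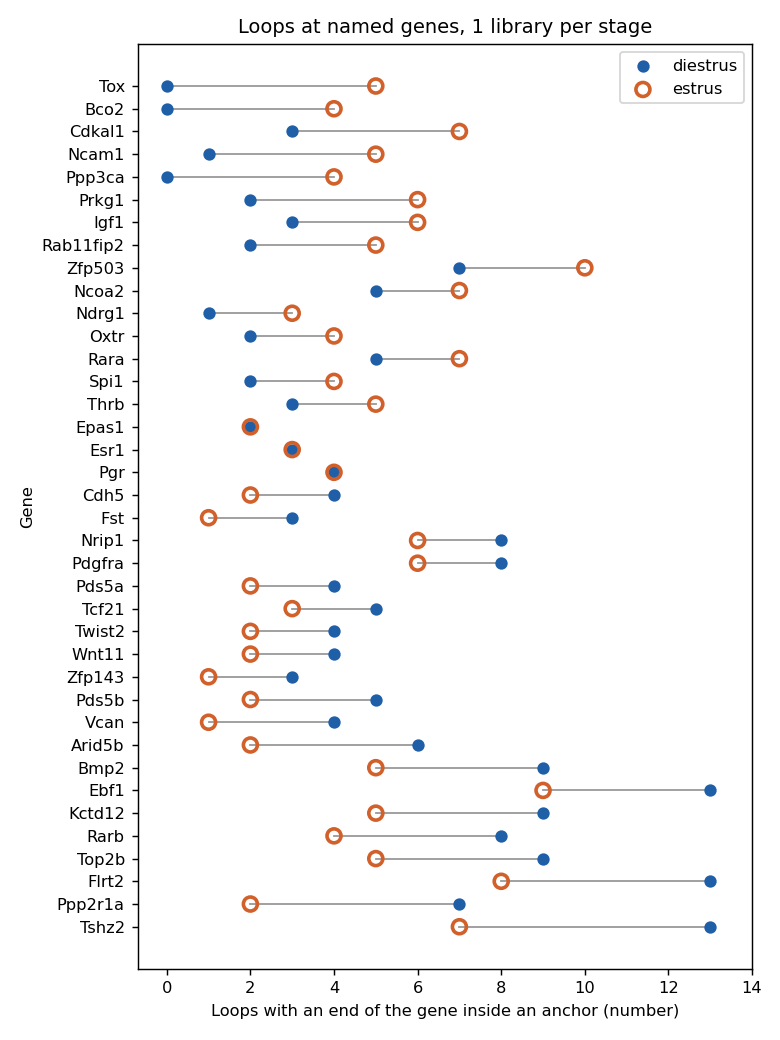
Number of loops with an end of the gene inside an anchor, for the genes named by rule, in the diestrus library (filled points) and the estrus library (open circles). Tshz2 had 13 and 7 loops, Tox had 0 and 5, which became 7 and 8 with gene ends within 5 kb, and Esr1, Pgr and Epas1 had equal numbers.

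Igf1, which encodes a growth factor that mediates uterine growth, had 3 loops in diestrus and 6 in estrus by the main assignment, and 5 and 6 with gene ends within 5 kb of an anchor or with any base of the gene in an anchor. All 3 diestrus loops at Igf1 were also called in estrus. The 3 further estrus loops ran from the gene's anchor at 87850001 to 87860000 on chromosome 10 (mm10) over 190 kb, 260 kb and 290 kb. They held 98 contacts (79.6 to 119), 88 contacts (70.6 to 108) and 78 contacts (61.7 to 97.3), at 2.11, 2.44 and 2.32 times the contacts expected from the local background. At Tox, a gene for a high-mobility-group nuclear protein on chromosome 4, the 5 estrus loops had ends of the gene in an anchor, while the diestrus loops lay at bins close by. The strongest of the Tox loops spanned 1170 kb and held 149 contacts (126 to 175), 7.01 times the expected number. A counterpart of 1 of the 5 Tox loops lay within 10 kb of it in the diestrus list, at a bin that holds no end of the gene.

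**Figure D2:**
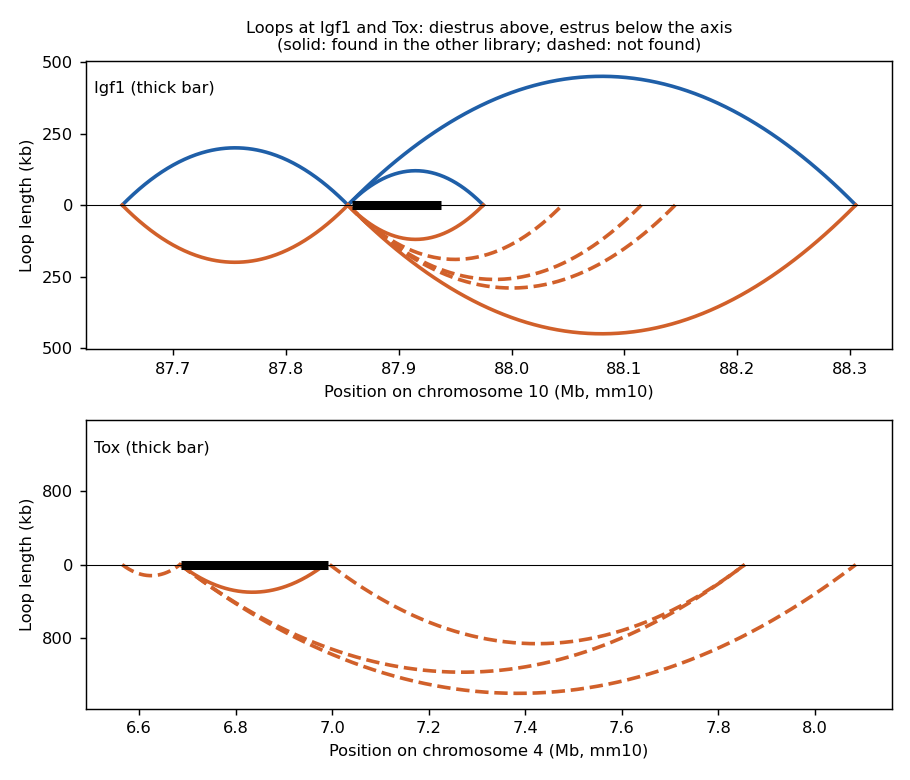
Loops with an end of Igf1 (upper panel) or Tox (lower panel) in an anchor, against position in Mb, with the height of each arc giving the loop's length in kb. Diestrus loops lie above the axis, estrus loops below it, and dashed arcs have no counterpart in the other library; Igf1 had 3 and 6 loops and Tox 0 and 5, against 5 and 6 and 7 and 8 with gene ends within 5 kb, which are not drawn.

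The gene for the decidual signal Bmp2 had 9 loops in diestrus and 5 in estrus, and Rarb, a retinoic acid receptor gene, had 8 and 4. With gene ends within 5 kb, Bmp2 had 9 and 7. At Bmp2, 7 of the 9 diestrus loops had a counterpart in estrus, some at a nearby bin. All 8 diestrus loops of Rarb left from the anchor at 16430001 to 16440000 on chromosome 14, which Rarb shares with Top2b, and 4 of them were found in estrus. The shared Rarb loop of 580 kb held 79 contacts (62.5 to 98.5) in diestrus and 97 (78.7 to 118) in estrus. Vcan, which encodes a matrix proteoglycan of the stroma, had 4 loops in diestrus and 1 in estrus. The Vcan loop present in both spanned 770 kb, with 149 contacts (126 to 175) and 107 (87.7 to 129).

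At Esr1, Pgr and Epas1, which the study concerns, the number of loops was equal in the 2 libraries by the main assignment, and under some but not all other settings. Esr1, the gene of estrogen receptor alpha, had 3 loops in each, of which 1 diestrus loop was found in estrus and 2 estrus loops in diestrus. It had 3 and 3 with gene ends within 5 kb or 10 kb, 8 and 11 with any base of the gene in an anchor, 3 and 2 with stricter q-values, and 1 and 3 with the diestrus list shortened to its strongest loops. The Esr1 loop with most contacts in estrus spanned 100 kb and held 698 contacts (647 to 752) at 4.67 times the expected number. Its paired diestrus loop lay at a nearby bin, and the centred log2 ratio of strength, estrus over diestrus, was 0.28. Pgr, the gene of the progesterone receptor, had 4 loops in each, or 7 and 6 with gene ends within 5 kb or 10 kb or with any base of the gene in an anchor, and 3 and 4 with the shortened diestrus list. The strongest Pgr loop, of 260 kb, held 476 contacts (434 to 521) in diestrus and 389 (351 to 430) in estrus, at 4.91 and 4.83 times the expected number. Epas1, which encodes the hypoxia-inducible factor HIF-2 alpha, had 2 loops in each at the same positions, or 2 and 3 with gene ends within 10 kb and 4 and 7 with any base of the gene in an anchor. The Epas1 loop of 50 kb held 285 contacts (253 to 320) in diestrus and 280 (248 to 315) in estrus, at 2.32 times the expected number in both.

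Genes of the chromatin loop machinery, the proteins that form and bound loops, had 25 loops in diestrus and 14 in estrus. Of these, 12 diestrus loops were found in estrus and 12 estrus loops in diestrus. Of the 19 members, 7 had more loops in diestrus, 1 had more in estrus, 2 had equal numbers, and 9 had no loop in either library. Pds5b had 5 and 2 loops, Pds5a had 4 and 2, and Ctcf, the gene of the main insulator protein, had 2 and 0. The 2 diestrus loops of Ctcf spanned 50 kb and 90 kb at 2.03 and 2.35 times the expected contacts. Zfp143 had 3 and 1, Smc3 had 2 and 3, and Stag2 had 3 and 3. The difference of -11 loops lay at percentile 0.05 of 10000 random lists of the same size and loop number, whose middle 95% ran from -7 to 5. This was the only list of 14 outside that range, and it describes these libraries alone. Without any single member the percentile stayed at or below 0.7, and without chromosome 7, which carries Zfp143 and Maz, the list had 21 and 12 loops at percentile 0.23. Counting loops with any base of a gene in an anchor gave 49 and 36 loops at percentile 3.005, inside the range.

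Stromal markers had 57 loops in diestrus and 45 in estrus. Of the members, 8 were higher in diestrus, 0 higher in estrus, 7 equal and 1 without a loop in either library. Besides Vcan, Pdgfra had 8 and 6 loops, or 10 and 9 with gene ends within 5 kb, and Twist2 had 4 and 2. The difference of -12 was at percentile 2.13, on the lower limit of -12 for random lists. Estrogen-responsive uterine genes had 62 and 67 loops, at percentile 96.2 and inside the random range of -13 to 6. In that list Igf1 had the largest difference, Wnt7a had 2 and 3 loops, Krt5 had 2 and 3, and Myc had 19 and 20. In the other direction, Aqp5 and Aqp8 each had 5 and 4. Of the members, 5 had more loops in estrus, 2 more in diestrus, 8 equal numbers and 17 no loop in either library. With q-values 10 times stricter this list had 57 and 64 loops, at percentile 98.7 and outside the random range, and with any base of a gene in an anchor it had 80 and 80, at percentile 78.4.

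The remaining lists lay inside the random range. Steroid receptors and coregulators had 34 and 28 loops, at percentile 12.9, with Nrip1 at 8 and 6 and Ncoa2 at 5 and 7. With the diestrus list shortened to its strongest loops the direction turned, to 26 and 28 loops at percentile 67.9, and Nrip1 had 6 and 6. Other nuclear receptors had 50 and 45 at percentile 25.2, with Rara at 5 and 7 and Thrb at 3 and 5. Progesterone-responsive and implantation genes had 74 and 70 at percentile 50.2, with Bmp2 as above, Fst at 3 and 1, or 4 and 3 with gene ends within 5 kb, Hoxa10 at 2 and 3 and Foxa2 at 3 and 2. The direction of this list turned as well, to 65 and 70 with the shortened list and 119 and 125 with gene ends within 10 kb, at percentiles 77.2 and 92.5. Genes of the Muellerian duct and uterine patterning had 71 and 71 at percentile 74.9, with Tcf21 at 5 and 3, Wnt11 at 4 and 2 and Wnt5a at 11 and 12. Wnt11 is on chromosome 7. This list had 66 and 60 loops with stricter q-values and 93 and 84 with any base of a gene in an anchor, at percentiles 29.9 and 26.9, and 67 and 71 with the shortened list, at percentile 73.2. Hypoxia and HIF genes had 20 and 22 at percentile 83.5, with Ndrg1 at 1 and 3. Counting loops with any base of a gene in an anchor put this list outside the range, with 33 and 40 loops at percentile 98.0. Immune and antimicrobial genes of the epithelium had 6 and 6 at percentile 60.7, and ubiquitously expressed genes had 8 and 8 at percentile 64.3. With gene ends within 10 kb these had 25 and 29, and 21 and 19. All these numbers are sums over members. Counted as distinct loops, the progesterone-responsive list had 72 and 68, the patterning list 65 and 65, and the immune and antimicrobial list 5 and 6.

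Among markers of the other cell classes of the uterus, smooth muscle markers had 39 loops in diestrus and 37 in estrus, at percentile 45.9, and the oxytocin receptor gene Oxtr had 2 and 4. Epithelial markers had 10 and 8 at percentile 29.1. With gene ends within 10 kb these lists had equal numbers, 44 and 44, and 19 and 19. Endothelial markers had 12 and 13 at percentile 75.2, or 22 and 21 with gene ends within 10 kb, with Cdh5 at 4 and 2, which was 2 and 2 with stricter q-values. Immune cell markers had 5 and 7 at percentile 91.4, with Spi1 at 2 and 4 as the only member that differed. The libraries came from whole uterus, and the share of each cell class in them is unknown.

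**Figure D3:**
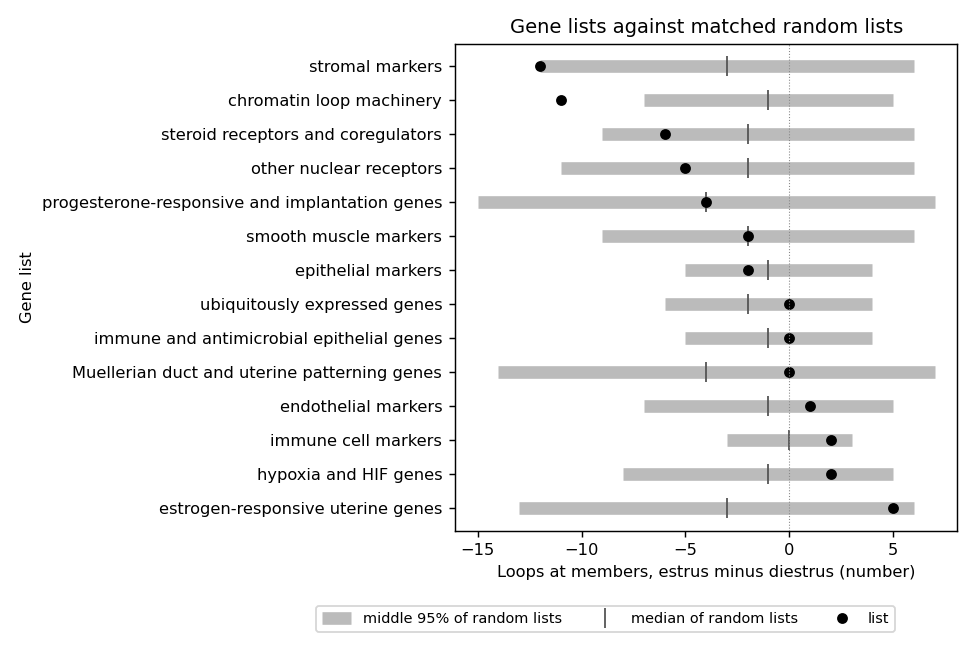
Loops at the members of each gene list, estrus minus diestrus (black points), against the middle 95% (grey bars) and the median (ticks) of 10000 matched random lists. The chromatin loop machinery at -11 lies below its range of -7 to 5, and stromal markers at -12 lie on the lower limit.

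Over the whole genome, estrus had 0.920 times as many loops as diestrus, or 47.9% of the 50371 loops of the 2 lists together (47.5% to 48.3%). Shared loops count in both lists, so this interval is no valid measure of chance. Contacts at called loops were 0.916 times as many in estrus, and the median log2 ratio of local background over shared pairs, estrus over diestrus, was -0.079. A lower depth in estrus would go in the same direction and was not tested. Of the diestrus loops, 19515 or 74.4% (73.8% to 74.9%) were found in estrus, and of the estrus loops, 19502 or 80.8% (80.3% to 81.3%) were found in diestrus. Random placement gave on average 3.77% and 4.10%. This left 6725 loops of the diestrus library alone and 4629 of the estrus library alone. Anchors were counted only at identical bins, without the tolerance used for loops. By this count 20318 anchors were in both lists, 77.0% of those in diestrus and 80.6% of those in estrus. Without the tolerance, 61.9% of diestrus loops and 67.3% of estrus loops were found in the other library. Of 49554 annotated genes, 11064 had an end in a loop anchor of both libraries, 2457 in diestrus alone and 1807 in estrus alone. Loops with a gene end in both anchors made up 17.9% (17.4% to 18.3%) in diestrus and 18.0% (17.5% to 18.5%) in estrus, and those with a gene end in 1 anchor 43.5% (42.9% to 44.1%) and 44.3% (43.7% to 45.0%).

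Loops called in a single library were weaker than shared loops. In diestrus their median of observed over expected contacts was 2.56 (2.54 to 2.58), against 3.68 (3.65 to 3.71) for shared loops, and in estrus it was 2.57 (2.55 to 2.60) against 3.74 (3.70 to 3.77). In the lowest decile of strength 39.7% (37.9% to 41.7%) of diestrus loops were found in estrus, and in the highest decile 95.5% (94.7% to 96.3%). The corresponding shares of estrus loops found in diestrus were 50.4% (48.4% to 52.4%) and 96.4% (95.6% to 97.1%). The extra estrus loops of Igf1 and the diestrus loops of Ctcf had strengths below the median of all loops, which was 3.28 (3.26 to 3.31) in diestrus and 3.43 (3.40 to 3.45) in estrus. The same held for the diestrus loops of Pds5b, Pds5a and Zfp143 not found in estrus, at 2.08 to 3.27.

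**Figure D4:**
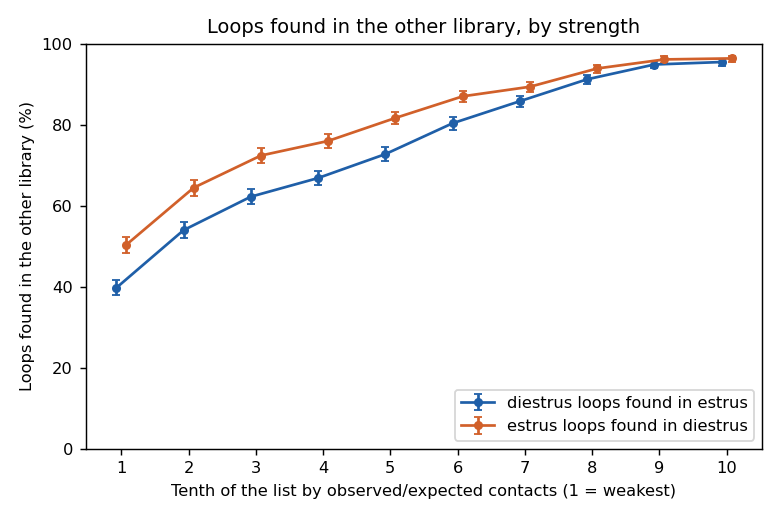
Percentage of loops found in the other library, against the decile of observed over expected contacts within each list, with exact 95% intervals. The share rises from 39.7% to 95.5% for diestrus loops (blue) and from 50.4% to 96.4% for estrus loops (orange).

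By length, the libraries had similar numbers of loops up to 100 kb, 4979 in diestrus and 4975 in estrus. Between 400 and 800 kb there were 4925 and 4308, a ratio of 0.875 (0.839 to 0.911). Over 2 Mb the numbers were again similar, 532 and 530, a ratio of 0.996 (0.882 to 1.13). The median length was 240 kb (240 to 250) in diestrus and 230 kb (230 to 240) in estrus. The local background at loops called at the same position differed by distance as well, with a median log2 ratio, estrus over diestrus, of -0.02 (-0.02 to -0.01) up to 100 kb, -0.13 (-0.14 to -0.12) between 400 and 800 kb, and -0.06 (-0.09 to -0.03) over 2 Mb.

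The strength of shared loops was compared over 19399 pairs, of which 16240 lay at the same position. The centred log2 ratio had an SD across loops of 0.26, and counting error alone gave 0.20. Over 1.5-fold, 319 loops were stronger in estrus and 302 in diestrus. Simulated counting error alone, over all 19399 pairs and with the backgrounds taken as exact, gave 123 and 103. Among the 16240 pairs at the same position, 113 loops were over 1.5-fold stronger in estrus and 116 in diestrus. These pairs are part of the 19399, so at most 123 and 103 of the simulated loops can be theirs, but the simulated loops were not counted apart for them. The SD of the centred log2 ratio over these pairs was 0.22, against 0.26 over all pairs. Across loops, which are not independent replicates, strength correlated between the libraries with Pearson's r = 0.939 and Spearman's rho = 0.907. Named pairs had at least 20 contacts in both libraries and an end of a protein-coding gene in an anchor of the diestrus loop. Pairs without such a gene were not ranked. Among ranked pairs, the 5 with the largest ratio towards diestrus were at Cyp2b19, Rhou, Rab11fip1, Usb1 and Cbr1. The Cyp2b19 loop was 2.62 times stronger in diestrus (1.89 to 3.67), with 133 contacts (111 to 158) against 53 (39.7 to 69.3), and the Rhou loop 2.41 times (2.06 to 2.82), with 561 (516 to 609) against 234 (205 to 266). Towards estrus the 5 were at Kifc3, Ceacam20, Ing5 and D2hgdh, Elk4 and Pcdh17. These are the genes at the diestrus anchors. By the main assignment Cyp2b19, Ceacam20, D2hgdh and Elk4 had no loop in estrus, since the paired estrus loop lay at bins without an end of the gene. The Kifc3 loop was 3.44 times stronger in estrus (2.98 to 3.99), although its contacts were 385 (347 to 425) in diestrus and 363 (327 to 402) in estrus. The loop at Ing5 and D2hgdh had a centred log2 ratio of 1.60 on the donut background and 2.41 on the bottom-left background. The size of the ratio also grew at Cyp2b19, Usb1 and Cbr1. It shrank at Ceacam20, Elk4 and Pcdh17, at Rhou from -1.27 to -0.99, at Rab11fip1 from -1.11 to -0.60 and at Kifc3 from 1.78 to 1.56. No direction changed. The Rab11fip1 loop held 86 contacts in diestrus and 112 in estrus, where 16.0 and 44.6 were expected. The expected contacts were 171 and 46.2 for the Kifc3 loop in diestrus and estrus, and 97.1 and 96.5 for the Rhou loop. All 10 of these loops were called at shifted positions in the 2 libraries, and Cyp2b19 and Ceacam20 are on chromosome 7.

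Among loops at the same position, where the genes to name were chosen after the lists were seen, the loop at Sox9, the gene of a transcription factor of gland cells, was 1.85 times stronger in estrus (1.44 to 2.38). It spanned 190 kb on chromosome 11 and held 98 contacts in diestrus and 191 in estrus. The loop at Tert was 1.80 times stronger in estrus (1.23 to 2.68), and that at Gpr149 2.01 times (1.28 to 3.22). In the other direction, the loop at Snai2 was 1.77 times stronger in diestrus (1.38 to 2.29), with 211 contacts in diestrus and 90 in estrus. The loop at Tshz1 and Zadh2 was 1.83 times stronger in diestrus (1.35 to 2.51), with 151 and 60 contacts, and that at Tent5a 1.78 times (1.32 to 2.42). Ratios larger than these in their direction were at Rnase2a and at Pramel22 and Pramel27. The Rnase2a loop was 2.16 times stronger in estrus (1.43 to 3.25), with 56 contacts in diestrus and 46 in estrus. These were 19.7 and 42.9 times the expected number. Its contacts were fewer in estrus, so this ratio came from the expected contacts. The loop at Pramel22 and Pramel27 was 2.01 times stronger in diestrus (1.20 to 3.42), with 37 and 28 contacts, at 8.23 and 4.12 times the expected number. A loop at Zfp949, Mthfsl and Bcl2a1d was 1.81 times stronger in diestrus, and that at Fam90a1a 1.79 times in estrus. All of these were picked from 16240 loops, so the largest ratios also hold the largest counting errors. Their intervals take the expected contacts as exact, and can be too narrow where few contacts are expected.

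Loops of a single library were ranked by observed over expected contacts among those with an end of a protein-coding gene in an anchor. The strongest of these were mostly long or thinly covered. Loops without such a gene were not ranked and can be stronger. In estrus, the strongest was a call between Cdc42se2 and the anchor of Nup85 and Gga3, over 60.87 Mb of chromosome 11. It held 36 contacts (25.2 to 49.8), where 0.131 were expected. The others in estrus were at Zfp141, Six2, Robo4 and Ntng1, with 20 to 62 contacts. In diestrus, a call between Ccdc6 and Gas2l3 over 19.25 Mb held 49 contacts (36.3 to 64.8), and loops at Zfp996, Slc8a1 and Rnaset2a held 25, 24 and 26 contacts. Whether calls over such distances are chromatin loops was not tested. The diestrus loop at 1600014C10Rik on chromosome 7 held 107 contacts (87.7 to 129).

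Chromosome 7 had the lowest ratio of loops, 1177 in estrus against 1448 in diestrus, or 0.813 (0.752 to 0.878). Of its 466 diestrus loops with at least 50 contacts and at least 4 times the expected number, 12.9% (9.97% to 16.3%) were not found in estrus, against 2.00% (1.69% to 2.34%) of 7408 on all other chromosomes. On the other chromosomes taken singly this share ran from 0.664% to 4.62%. In the reverse direction, 1.21% (0.394% to 2.80%) of 413 such estrus loops on chromosome 7 were not found in diestrus. The loop that joined Tm2d3 and Pcsk6 over 350 kb of chromosome 7 held 463 contacts (422 to 507) in diestrus, 11.6 times the expected number, and was not in the estrus list used here. Without chromosome 7 the libraries had 24792 and 22954 loops, 74.8% and 80.7% of them were shared, and genes in anchors of diestrus alone and estrus alone numbered 2188 and 1698.

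**Figure D5:**
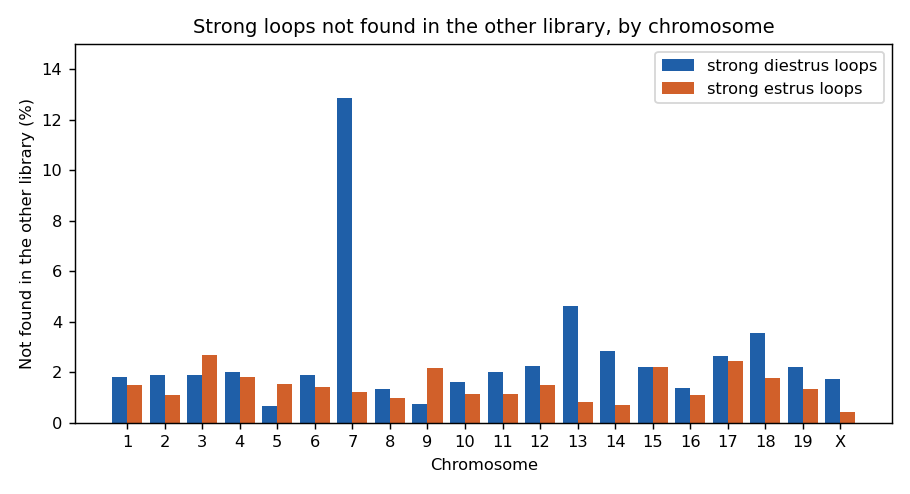
Percentage of loops with at least 50 contacts and at least 4 times the expected number that were not found in the other library, by chromosome, for diestrus loops (blue) and estrus loops (orange). For diestrus loops chromosome 7 stands at 12.9%, and the highest of the other chromosomes at 4.62%.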

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

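Settings without chromosome 7 and with any base of a gene in an anchor were chosen after the data were seen, as was shortening the longer list for the named genes. No paired analysis was possible because each group has 1 library, and leaving out a replicate could not be run for the same reason. Loop numbers in both libraries stayed within 1.5 times under all alternatives run, and the share of all loops that were in estrus moved outside its interval only for loops of more than 1 pixel, to 48.5%. The shares of diestrus and estrus loops found in the other library were 61.9% and 67.3% when anchors had to overlap, 76.7% and 82.9% at 25 kb, 81.6% and 87.4% at 50 kb, 73.6% and 79.8% with q-values 10 times stricter in both lists, and 76.4% and 82.4% with them stricter only in the list looked up. With the longer list shortened to its strongest loops the shares were 77.5% and 77.6%, nearly equal by construction, since the lists are then of 1 length and about as many loops are shared in either direction. At identical positions, 113 shared loops were over 1.5-fold stronger in estrus and 116 in diestrus, with an SD of 0.22; the bottom-left background gave an SD of 0.27. Median observed over expected contacts in diestrus and estrus were 3.16 and 3.29 on the bottom-left background and 2.42 and 2.49 on the largest background. Genes in anchors of both libraries numbered 16724 with gene ends within 5 kb and 20892 within 10 kb. For protein-coding genes only there were 6638 in both, 1410 in diestrus alone and 1001 in estrus alone. With gene ends within 5 kb, 32.5% of diestrus and 33.8% of estrus loops had a gene end in both anchors, and 44.3% of diestrus loops had it in 1 anchor. For protein-coding genes these shares were 9.25% and 9.22% for both anchors and 34.6% and 35.5% for 1 anchor. These gene shifts follow from counting more or fewer genes; for the other changes the cause was not tested. With stricter q-values 2 gene lists lay outside the random range. Of 35 named genes with a difference, 3 lost its direction under at least 1 of 5 settings. For Prkg1 the difference was -2 loops with any base of the gene in an anchor, opposite to the reported one, Cdh5 had 2 and 2 loops with stricter q-values, and Nrip1 had 6 and 6 with the shortened list. Another 11, including Tox, Ppp3ca, Igf1 and Zfp503, kept it with a difference of 1 loop in some setting. The differences of the steroid receptor, progesterone-responsive and endothelial lists changed sign under at least 1 setting. Alternatives by anchor width were not run because all anchors are 10 kb wide, and the motif alternatives were not run. Depth limits which weak loops are called, and 59.2% of the loops of diestrus alone and 60.1% of those of estrus alone were a single pixel.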

Other observations

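All tests in this part were chosen after the patterns had been seen. Cwc22, which encodes a splicing factor, lies at 77881159 to 77946356 on chromosome 2, inside a loop of 150 kb. That loop had more contacts than any other in both libraries, 2043 (1955 to 2134) in diestrus and 4201 (4075 to 4330) in estrus, and the next loop in estrus held 1524.

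The doubled contacts at Cwc22 could come from a stronger loop or from extra copies of the segment in the animals used. The centred log2 ratio of strength was 0.18 (0.10 to 0.26), far below the log2 ratio of contacts of 1.04, which argues against a stronger loop as the whole cause. The local background rose with the contacts, by 0.85 on the log2 scale, more than at any of the 6479 loops at identical positions with an expected number of at least 50, whose middle 95% ran from -0.37 to 0.19. The 16 other loops within 1 Mb had background ratios of -0.25 to 0.18. Extra copies in these outbred animals are therefore a candidate explanation, which would be a difference between animals, and a stage-related rise in contacts over the whole segment was not tested.

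The strong diestrus loops of chromosome 7 missing from the estrus list could reflect fewer reads, weaker looping, bins left out of calling, anchors lost in estrus, or estrus loops that are not among those used here. At loops called at the same position in both libraries, the median log2 background ratio on chromosome 7 was -0.078, within the range of -0.095 to -0.032 of the other chromosomes. The median centred log2 ratio of strength of its strong loops among these was -0.018, within -0.066 to 0.008. These values argue against fewer contacts and weaker looping along the whole chromosome. Missing loops are not among those compared, so the values cannot address a loss confined to part of it. Of the 60 missing loops, 48 or 80.0% (67.7% to 89.2%) had an anchor that no estrus loop used within 20 kb, against 36.5% (28.7% to 44.8%) of 148 missing loops elsewhere, consistent with bins left out of calling in estrus; loss of single anchors in estrus, or estrus loops that are not among those used here, would give the same count of 48 and cannot be told apart from the lists alone. Over 9 pairs of limits on strength and contacts, from 10.4% to 23.0% of the chromosome 7 loops were missing, above every other chromosome in all 9. Gene differences on chromosome 7, such as at Cyp2b19, Zfp143, Wnt11 and Pcsk6, carry this doubt.

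Loops called in a single library may be loops of both stages that passed the caller's limit in only 1. The share of diestrus loops found in estrus was 55.8 percentage points higher in the highest than in the lowest decile of strength, as such a limit would give. Stage-specific weak loops would also fall among the weakest, so a biological part remains open and untested without replicates. The differences at Igf1, at Rarb and at the chromatin loop machinery, Ctcf included, rest largely on loops of this kind.

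Loops over 10 Mb numbered 76 in diestrus and 74 in estrus, and 52 of each were found in the other library. Their median of observed over expected contacts was 132 in diestrus and 174 in estrus, on expected numbers of 0.187 and 0.151. Whether these calls are chromatin loops was not tested.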
